A study of Scophthalmus maximus with 16 samples.

How the data were processed

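RNA from the head kidney of turbot (Scophthalmus maximus), the main blood-forming and lymphoid organ of bony fish, was measured on 16 single-colour Agilent arrays. Per the labels, 6 families from a fish farm were injected with viral haemorrhagic septicaemia virus (VHSV), a rhabdovirus of fish, or with culture medium, and 4 families were kept, 2 with the highest and 2 with the lowest mortality. Which of the 4 was which is not given in the sources used here. Fish of each family received VHSV or medium on day 0, and survivors and medium-injected fish received VHSV or medium on day 30. Head kidneys were taken 24 h after the second injection, and RNA of 5 fish was pooled for each array, so each of the 4 treatment groups holds 4 pools, 1 per family. The spread between arrays is therefore a spread between pools of different families, and the spread between single fish was not measured.

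The deposited scanner files hold spot intensity values that, per the file headers, Agilent Feature Extraction 9.5.1.1 made with spatial and multiplicative detrending and no local background subtraction. The flags for outlier spots, saturation and signal well above background were set by the same software, per the file headers. A deposited table of the whole series holds log2 values whose processing is not given in the sources used here. Its columns were set against the scanner values. They matched log2 intensity minus the 75th percentile of each array, centred on the median of each spot over the 16 arrays, with Pearson r of at least 0.9999 over spots and a largest difference of 0.03 on the log2 scale. Medians of its columns lay between -0.09 and 0.08. Its scale, centring and direction were thus found from the values and are not stated.

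Each array had 14501 spots, of which 13965 were not controls. These belonged to 4305 probes, 4155 printed in 3 spots and 150 in 10. The probes were 46 to 60 nt long and had 4161 distinct sequences, and 168 probes shared their sequence with another. Every probe is described as unknown in the scanner files, and the gene table used here holds neither probe IDs nor probe sequences, so probes are reported by ID and sequence. For the same reason the 24 gene lists and the cell type markers fixed before the data were examined could not be matched to probes, and no list was tested.

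The computation started from log2 of the processed intensity minus the 75th percentile over the non-control spots of each array. Spots marked as outliers, 262 to 377 per array, were left out and the other spots of a probe were averaged. A probe was tested when over 0.5 of its spots were well above background on at least 4 of the 16 arrays. This kept 4098 probes and removed 207. No non-control spot was saturated. Median SD between spots of a probe was 0.06 to 0.08 on the log2 scale, which leaves out labelling and hybridization, and the median residual SD between pools was 0.29. The number of pools limits the precision.

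Models were fitted with limma 3.58.1 in R 4.3.3, with default empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. All 16 arrays entered each fit. Treatment group and family were fixed terms, which left 9 residual degrees of freedom. The 5 treatment contrasts came from this fit, and family was tested by an F test with treatment group as covariate. An F test of the family by second injection interaction, with 6 residual degrees of freedom, asked whether the response to VHSV differed between families. Family was used as a block because the labels say that fish of each family were divided over the treatments; no statistical model is given in the sources used here. Pools of the same family also deviated together. The correlation of their deviations from the group means had a median of 0.31 over 24 pairs, with a range from -0.30 to 0.73 and 18 pairs above 0.1. Pools of different families had a median of -0.08 over 72 pairs, and 14 of the 16 arrays correlated best with a pool of their own family. All pools of a family were on the same slide and most pairs of different families were not. Slide may therefore add to the difference between these medians. The fit with no replicate block was an alternative and called 0 probes in each of the 5 treatment contrasts, as did the fit with the block.

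Families 1 and 2 were on 1 slide and families 3 and 4 on the other. Each treatment group occupied the same column on both slides in every family, so position on the slide and treatment cannot be told apart. With no gene names, the rule fixed before the data were examined allows at most 2 probes in each direction per comparison. How these were ranked was set afterwards: for treatment contrasts, by the smallest p among probes that differed one way in all 4 families, and for the family tests by the smallest p. For a probe not well above background on every pool of a family, the ratio is given as a lower bound. It sets the mean of the brighter family against, per array, the higher of the probe's own value and the lowest signal among probes well above background.

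The same functions were tested on simulated data with the real means and residual SD of 4095 probes. In each simulated set, 50 probes were changed at each of 4 fold sizes, all at once. At 2-fold, 56.0% of the changed probes were recovered for the naive response, 80.0% for the response of survivors, 60.0% for prior exposure, 68.0% for the 2 infected groups, 38.0% for the interaction, 64.0% for the family difference and 6.00% for the family by infection test. At 4-fold these shares were 88.0%, 94.0%, 90.0%, 94.0%, 80.0%, 86.0% and 52.0%. The first 4 contrasts each set 4 pools against 4 with the same spread. Differences between their shares come from single runs of 50 probes and are not differences in sensitivity. Of the unchanged probes, 0 to 6 were called in a treatment contrast, 15 for the family difference and 2 for the family by infection test. The simulation gave every pool the same spread and drew the values of each probe independently of the other probes. Recovery may be lower where fewer probes change, and probes in the real data vary together.

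Alternatives chosen before the data were examined were normexp background correction with an offset of 50, quantile normalization, median centring, the deposited log2 values, no filter and a filter at 12 arrays, no family block, slide as block, only the groups compared, a trended and robust variance, a 2-fold minimum, and leaving out each family and each array. Averaging probes of a gene was not possible without gene names. Array weights, leaving out both control pools of family 4, each slide alone, the level of a set of covarying probes as covariate and 1 value per sequence were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.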

Results

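Head kidney expression was measured in 16 pools of 5 turbot, from 4 families that each contributed a pool to 4 treatments. Naive control pools received medium on days 0 and 30, and naive infected pools received medium and then VHSV. Survivor control pools, called resistant in the labels, received VHSV and then medium, and survivor infected pools received VHSV on both days. The 75th percentile of the signal ranged from 4362 in the naive infected pool of family 3 to 13238 in the naive infected pool of family 1. Between 89.2% and 95.4% of probes were well above background on an array. Pearson correlation between arrays over probes, which are not independent replicates, ranged from 0.832 to 0.989 with a median of 0.970. The first principal component held 49.4% of the variance. On it the naive control pool of family 4 lay at 80.7 and its survivor control pool at 35.7, with the other pools between -39.3 and 26.4.

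The response of naive fish to a first encounter with VHSV was read from the naive infected against the naive control pools. Probe R2_1892 (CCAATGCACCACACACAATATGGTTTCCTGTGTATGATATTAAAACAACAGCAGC) was 1.75-fold higher in infected pools, at -1.76 ± 0.52 against -2.57 ± 0.21 on the log2 scale relative to the 75th percentile (SD, n = 4). R2_2165 (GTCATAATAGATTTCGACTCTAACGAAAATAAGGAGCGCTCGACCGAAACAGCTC) was 1.73-fold higher. R2_5839 (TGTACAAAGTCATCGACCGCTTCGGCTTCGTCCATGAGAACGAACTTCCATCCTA) was 1.51-fold lower and R2_371 (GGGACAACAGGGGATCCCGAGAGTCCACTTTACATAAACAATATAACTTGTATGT) 1.48-fold lower. Each of these probes was chosen among those that differed in the same direction in all 4 families. That held for 13.5% of probes, where 12.5% are expected by chance. None of the 4 passed the test, with an adjusted p of 0.708 in limma for each. Of the 4098 probes, 0 were called, and 235 had an unadjusted p under 0.05 where 204.9 are expected by chance. No probe differed at least 2-fold one way in all 4 families, although 278, 488, 386 and 571 probes did so within families 1, 2, 3 and 4. Without family 3, or without either of its naive pools, 71 probes did, against 11 without family 1 and 2 without family 4. Fewer families then had to meet the condition, so these counts could not fall. Pearson r between the responses of pairs of families, across probes, ranged from -0.37 to 0.30. The 95% interval of a change extended a median of 0.44 either side on the log2 scale, or 1.36-fold. With slide as block and within each slide the count was also 0.

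In survivors, the response to a second dose of VHSV was read from the survivor infected against the survivor control pools. R2_1023 (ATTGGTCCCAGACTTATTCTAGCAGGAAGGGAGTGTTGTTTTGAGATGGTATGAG) was 2.88-fold higher after VHSV, a difference of 1.52 ± 0.50 (SE) on the log2 scale. R2_4066 (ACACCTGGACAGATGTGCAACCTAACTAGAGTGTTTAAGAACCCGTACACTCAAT) was 2.45-fold higher, by 1.30 ± 0.36. R2_2415 (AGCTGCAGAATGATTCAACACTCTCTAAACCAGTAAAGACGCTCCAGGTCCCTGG) was 1.61-fold lower and R2_492 (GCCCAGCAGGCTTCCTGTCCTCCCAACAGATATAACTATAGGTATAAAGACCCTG) 1.56-fold lower. These 4 probes were chosen among those that differed in the same direction in each of the 4 families, which 7.78% of probes did. By chance 12.5% are expected. Each of the 4 had an adjusted p of 0.99998 in limma. Of 4098 probes, 0 were called and 56 had an unadjusted p under 0.05, where 204.9 are expected by chance. Within the slide of families 1 and 2 alone, with 3 residual degrees of freedom, 5 probes were called, all lower after VHSV by -4.71 to -5.32 on the log2 scale; within the other slide and with slide as block 0 were called. In family 3 the same 5 probes differed by 2.41 to 3.40 in the opposite direction, and in family 4 by -0.98 to 0.57. The 5 include R2_106 and R2_1821, a choice made after their values were seen.

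**Figure D1:**
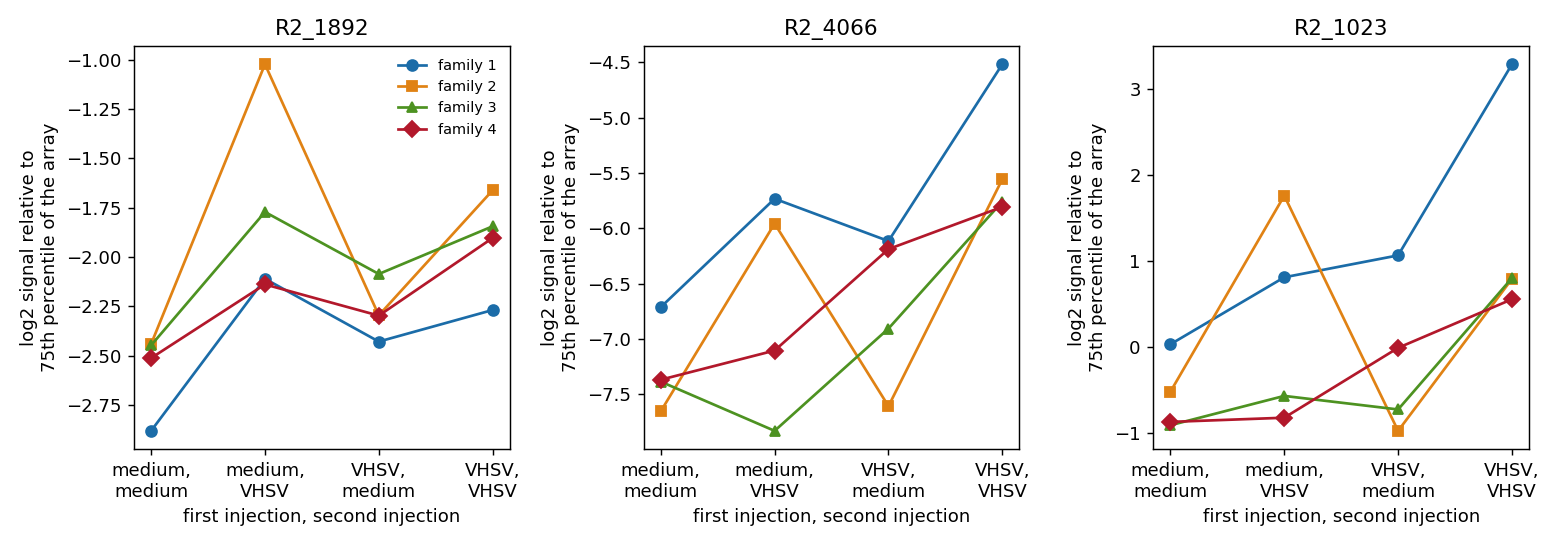
Log2 signal relative to the 75th percentile of the array for probes R2_1892, R2_4066 and R2_1023 in each of the 16 pools, by first and second injection, with 1 line per family. R2_1023 reached 3.29 in the survivor infected pool of family 1 and between 0.55 and 0.80 in the other survivor infected pools.

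The responses of naive fish and survivors were set side by side, since they share no array. Their mean changes correlated across the 4098 probes at a Pearson r of 0.689 and a Spearman rho of 0.426, and probes are not independent replicates. Without family 4 the Pearson r was 0.274, without its survivor infected pool alone 0.333, and in families 1 and 2 alone 0.236. Within single families it was -0.09, 0.39, -0.12 and 0.76 in families 1 to 4. The difference between the 2 responses was tested as an interaction, and 0 probes were called. An unadjusted p under 0.05 was found for 61, where 204.9 are expected by chance, and the smallest adjusted p was 0.999 in limma. R2_2165 differed by -1.16 ± 0.27 (SE) on the log2 scale, survivors minus naive, and was lower in all 4 families. R2_4176 (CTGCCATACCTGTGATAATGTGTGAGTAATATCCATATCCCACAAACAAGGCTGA) differed by 0.92 ± 0.27 and was higher in all 4. Both were chosen for differing one way in all 4 families, as 7.76% of probes did where 12.5% are expected by chance. Neither passed the test. The 95% interval extended a median of 0.63 either side, or 1.55-fold, which is wider than for the single responses. The count was 0 with slide as block and within each slide.

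The difference between survivors and naive fish after 30 days was read from the survivor control against the naive control pools. A group of 38 probes was at least 2-fold lower in survivors in all 4 families, and 0 were at least 2-fold higher. Their median difference was -4.06, -1.93, -1.30 and -2.57 on the log2 scale in families 1 to 4. All 38 belong to a larger set of 177 probes that were over 16-fold higher in the naive control pool of family 4 than the median of the other pools. The limma test called 0 of the 4098 probes, with a smallest adjusted p of 0.999. An unadjusted p under 0.05 was found for 174, where 204.9 are expected by chance. Outside that group, R2_1835 (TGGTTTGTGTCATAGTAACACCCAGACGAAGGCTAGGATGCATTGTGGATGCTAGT) was higher in survivors by 0.59 ± 0.13 (SE) on the log2 scale and R2_995 (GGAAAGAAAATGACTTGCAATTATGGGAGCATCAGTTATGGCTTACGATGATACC) was 1.52-fold higher. R2_3482 (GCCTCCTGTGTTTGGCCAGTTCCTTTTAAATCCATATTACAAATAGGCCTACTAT) was 1.65-fold lower and R2_2975 (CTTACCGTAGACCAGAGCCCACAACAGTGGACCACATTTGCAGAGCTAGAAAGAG) 1.64-fold lower. None of these passed the test. Counted in either direction, probes at least 2-fold one way in all families numbered 16 with normexp background correction. They numbered 89 without family 3, where fewer families had to meet the condition. With slide as block and within each slide the limma count was 0.

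Both infected groups were then compared by their first injection. R2_4176 was 1.80-fold higher in survivors than in naive fish, at -6.26 ± 0.32 against -7.11 ± 0.34 (SD, n = 4). R2_1630 (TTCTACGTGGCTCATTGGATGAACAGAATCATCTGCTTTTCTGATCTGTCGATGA) was 1.91-fold higher. R2_4209 (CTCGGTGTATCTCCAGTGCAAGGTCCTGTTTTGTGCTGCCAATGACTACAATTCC) was 1.91-fold lower and R2_492 was 1.64-fold lower. All 4 differed one way in each family, and none passed, at an adjusted p of 0.992 in limma. Of 4098 probes, 0 were called and 97 had an unadjusted p under 0.05, where 204.9 are expected by chance. A group of 14 probes was at least 2-fold lower in survivors in all 4 families, 12 of them among the 177 probes high in the naive control pool of family 4. Probes 2-fold one way in all families, higher or lower, numbered 3 with normexp background correction and 6 with quantile normalization. Without family 1, 2 or 4 they numbered 48, 22 and 30, where fewer families had to meet the condition, so these counts could not fall. The limma count was 0 with slide as block and within each slide.

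Families, which had been chosen for their mortality, differed in 93 probes by the limma F test at adjusted p under 0.05, and 66 of these spanned more than 2-fold between families. Families 1 and 2 shared 1 slide and families 3 and 4 the other, so in this test the difference between those pairs cannot be told apart from that between slides. Family 1 stood farthest from the median of the families in 48 of the 93 and family 4 in 31. Within the first slide, 8 probes were higher and 7 lower in family 2 than in family 1. R2_1183 (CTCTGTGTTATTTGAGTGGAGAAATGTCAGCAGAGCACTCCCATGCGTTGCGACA) was 6.70-fold lower in family 2, at -6.86 ± 0.29 against -4.12 ± 0.11 (SD, n = 4), with an adjusted p of 2.52e-05 in limma. R2_3180 (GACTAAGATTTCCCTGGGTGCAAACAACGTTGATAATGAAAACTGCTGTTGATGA) was 3.52-fold lower. R2_4079 (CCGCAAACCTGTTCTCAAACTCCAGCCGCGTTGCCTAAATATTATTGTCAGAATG) was 2.33-fold higher and R2_1271 (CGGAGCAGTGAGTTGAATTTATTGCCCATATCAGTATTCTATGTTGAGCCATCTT) 2.02-fold higher. Within the other slide, 3 probes were higher and 5 lower in family 4 than in family 3. R2_3631 (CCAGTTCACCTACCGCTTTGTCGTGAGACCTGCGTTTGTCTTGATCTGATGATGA) was 5.44-fold lower in family 4, with an adjusted p of 0.000783 in limma, and R2_4529 (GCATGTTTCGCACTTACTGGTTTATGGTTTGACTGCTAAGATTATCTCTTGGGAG) was 5.09-fold lower. R2_4013 (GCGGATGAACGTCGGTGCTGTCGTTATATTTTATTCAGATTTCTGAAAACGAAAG) was 2.00-fold higher. R2_3588 (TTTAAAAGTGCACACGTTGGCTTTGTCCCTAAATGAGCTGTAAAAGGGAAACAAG) was well above background in 4 of 4 pools of family 4 and in 0 of 4 of family 3, and was at least 2.86-fold higher. With normexp background correction the difference of R2_3588 was 0.53 on the log2 scale, below that bound, and was no longer called. Quantile normalization gave 10 higher and 3 lower on the first slide and 6 and 4 on the other, and median centring gave 14 and 7, and 7 and 5. The 15 calls between families 1 and 2 became 26 with a trended and robust variance, 89 with array weights, 5 without family 3, 31 without family 4 and 32 without the control pools of family 4. They became 7 without the naive infected or survivor infected pool of family 1 or any pool of family 2 but the naive infected one, 9 without the survivor control pool of family 1, and 29 and 24 without the naive control and survivor infected pools of family 4. The 8 calls between families 3 and 4 became 14 with array weights, 5 without family 2 and 4 without the control pools of family 4. The F test over all families called 60 probes with median centring, 276 with array weights and 38 without the control pools of family 4, and 14, 46, 27 and 37 without family 1, 2, 3 and 4. Leaving out any single pool other than the infected pools of families 2 and 4 and the survivor control pool of family 2 moved it by over 1.5 times. Families 1 and 2 fitted alone gave 2 calls, and families 3 and 4 alone gave 0. With unchanged differences but 3 residual degrees of freedom, R2_3180, R2_4079, R2_1271 and the 4 probes named for the other slide then lost their calls. R2_4079 also lost its call with the deposited values, at 1.22 on the log2 scale in both. These keep a spot marked as an outlier in the naive control pool of family 4, and its residual SD rose from 0.19 to 0.88. R2_1271 lost it without family 3, at an unchanged 1.01 and an adjusted p of 0.0501 in limma. R2_4529 lost it without the control pools of family 4, at -2.38 against -2.35, and R2_4013, at 0.997, with a 2-fold minimum.

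**Figure D2:**
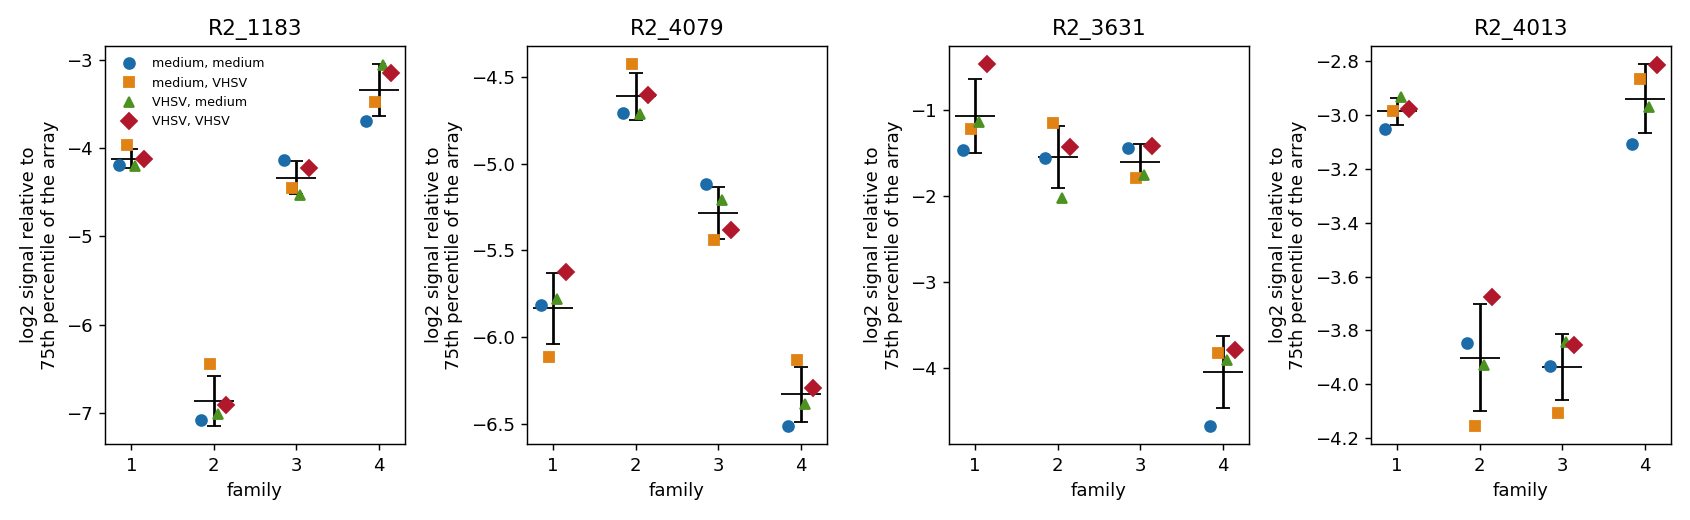
Log2 signal relative to the 75th percentile of the array for 4 probes that differed within a slide, in the 4 pools of each family, with symbols for the first and second injection. Horizontal bars are means and error bars SD over 4 pools. R2_1183 averaged -6.86 in family 2, and R2_3631 averaged -4.05 in family 4.

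Whether the response to VHSV differed between families was tested with the interaction of family and second injection. This called 37 of the 4098 probes, and all 37 were lower after VHSV in family 4, in naive fish and in survivors. The median change in family 4 was -6.08 on the log2 scale in naive fish and -5.15 in survivors. In family 3 the medians were 0.98 and 0.58, in family 2 -0.86 and -0.92, and in family 1 -2.61 and -0.10. R2_1022 (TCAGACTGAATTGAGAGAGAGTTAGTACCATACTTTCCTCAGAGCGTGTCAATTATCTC) was 23.0-fold lower after VHSV in naive fish of family 4 and 47.3-fold lower in survivors, with an adjusted p of 0.010 in limma. R2_1822.1 (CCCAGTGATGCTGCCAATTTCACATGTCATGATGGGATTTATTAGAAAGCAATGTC) was 79.9-fold and 243-fold lower, with an adjusted p of 0.010 in limma. In the control pools of family 4 the 37 probes averaged -1.06 and -2.93, against -3.93 to -8.51 in the other 14 pools. When the differences of survivors after VHSV were exchanged between families, 4 of the 24 arrangements, the real one included, called 37 or more probes. Of the 37, 35 belong to the set of 177 probes high in the naive control pool of family 4. The count was 22 with quantile normalization and 61 with a trended and robust variance. It was 0 without family 3, without family 4 or without either infected pool of family 4, 3 without its naive control pool, 15 without family 2 and 143 without family 1. It was 0 within the slide of families 1 and 2 and 134 within that of families 3 and 4, and leaving out any single pool other than the naive infected pool of family 1, the survivor control pool of family 4 and 3 pools of family 2, all but its naive infected pool, moved it by over 1.5 times.

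**Figure D3:**
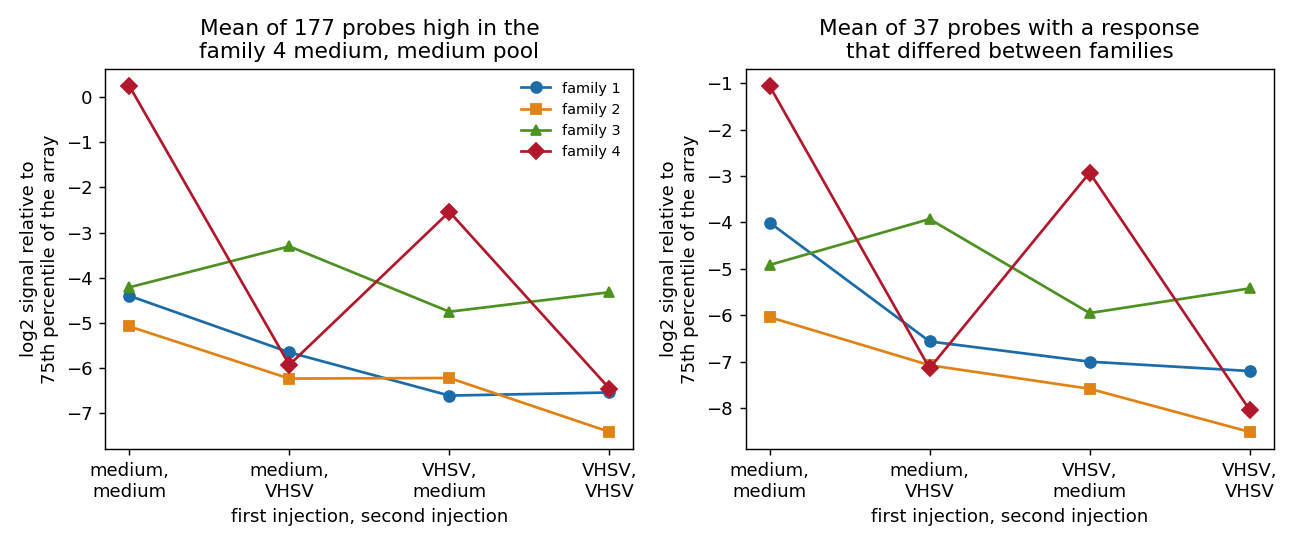
Mean log2 signal relative to the 75th percentile of the array over 177 probes (left) and 37 probes (right) in each of the 16 pools, by first and second injection, with 1 line per family. In family 4 the mean of the 177 probes was 0.25 and -2.54 in the control pools and -5.92 and -6.45 after VHSV.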

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

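The weighing of the 177 probes, of the 38 probes lower in survivor controls and of the 37 probes with a differing response used tests chosen after the result was seen. The exchange of differences between families was also chosen afterwards, and the other counts over splits of the pools were planned before those splits were run. Dixon's ratio was computed for groups of 4 pools. Leaving out the means of probe sets chosen from these data, whose outliers their choice can fix, 9 of 120 groups exceeded its 95% critical value, where about 6 are expected by chance. Of the 12 groups of set means, 2 exceeded it.

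The 177 probes averaged 0.25 on the log2 scale in the naive control pool of family 4, against -5.07 to -4.21 in the other naive control pools, 60.96-fold above the median of the 14 pools other than the control pools of family 4. A scaling error of that array could not be tested by the level of its other probes. Each array had been scaled to a percentile of its own signal, which holds most of its probes near a common level. The median deviation of the other tested probes, -0.19 (SD 0.77 over probes), therefore decides nothing about scaling. A slide or scan effect as the whole cause is argued against. Over the other 7 arrays of the slide, the set deviated by a median of 1.36 (SD 1.37 over arrays), with 2 arrays below 0. A single admixed source of RNA with 1 profile in both control pools of family 4 would give every member the same share of its excess in the survivor pool. The SD of the log2 of that share was 1.75 over 168 members. For the plain log2 difference between both pools, the SD was 1.35 over the members and 0.70 over the other probes. The members also varied in families 1 to 3, with an SD of 2.98, 1.21 and 0.94 for the same difference. Their spread in family 4 therefore decides nothing about a single source. Such a source stays open. So do a source whose profile differed between the pools, which held different fish, and several sources, such as other tissue in some fish. A difference in physiology of these fish also stays open, and without gene names or single fish these could not be told apart.

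The 38 probes at least 2-fold lower in survivor controls were set against the same count with the direction turned in some families. Of the 8 sign patterns, 1 gave 38 or more, the highest of the others gave 10, and 8 patterns cannot give a share under 0.05. The 177 probes had a median of -0.72 or lower in each of families 1 to 3. They include all 38, which were chosen for being lower there, so these medians decide nothing about the cause. The difference of a family uses only its own pools. Without the naive control pool of family 4, 39 probes were at least 2-fold one way, higher or lower, in the remaining families. The 38 meet that condition by their choice, so this count could not fall below 38. It decides nothing about that pool as the cause, and chance is not excluded. Why all 38 lie in the set high in that pool was not tested. An effect of the earlier infection may be involved. Position on the slide and the selection of fish that lived through it cannot be told apart from that effect, and the limma test called 0 probes. The mean level of the 38 probes was also out of place in 1 other pool, the naive infected pool of family 3, at -3.34 against -7.03 to -6.58 in the other naive infected pools.

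The response to VHSV differed between families in 37 probes by the test of the interaction itself. Among families 1 to 3 it called 0 probes, but it also called 0 without family 3 and 15 without family 2. Without family 3 the changes of R2_1022 and R2_1822.1 in family 4, which do not use that family, stayed at -5.04 and -7.12 and their calls ended, while both stayed called without family 1 or family 2; why the calls depend on family 3 was not tested, and whether family 4 alone carried the difference stays open. Exchanging the differences of survivors after VHSV between families, which keeps the family levels, gave 37 or more in 4 of 24 arrangements, the real one included, with a highest other of 112, so chance is not excluded. Of 100 draws of the family labels within groups, which also part the family levels and so do not test the interaction alone, 4 gave 37 or more and the highest other gave 163.

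Of 35 splits of the pools, all 35 gave at least the 0 calls of the naive response, with a highest other of 1. The same held for the response of survivors, 35 of 35 with a highest other of 1. No split or draw can give under 0 calls, so shares set against a real count of 0 were fixed beforehand and test nothing. For the 2 infected groups all 35 gave 0. For prior exposure all 35 gave 0 or more, and 1 split gave 68, with the naive control pools of families 1, 2 and 4 and the survivor control pool of family 4 on 1 side. That split differs from treatment by an exchange of 2 pools, and its count points to a structure of the pools whose cause was not tested. Among the 8 splits that part all family pairs, the highest other was 0 for the naive response, 1 for survivors, 0 for prior exposure and 0 for the infected groups. All 100 draws of the treatment labels within families gave at least the 0 calls of the interaction, with a highest other of 1. Of 100 draws of the family labels within groups, 3 gave 93 or more probes differing between families, the real one included. The highest other gave 134. That share is under 0.05, but 100 draws estimate it only roughly, so chance is less likely and not excluded. These draws do not part family from slide, so the slides may have added to the 93.

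Other single pools stood apart within their group. On the second principal component the naive control pool of family 1 lay at 37.9, the others at -6.93 to -1.20. R2_1892 was -2.88 in the naive control pool of family 1, and R2_625 was -6.81 there. R2_1023 was 3.29 in the survivor infected pool of family 1, and R2_1835 was -6.89 in the survivor control pool of family 3. Within families, R2_3631 was -4.68 in the naive control pool of family 4, and R2_4529 was -3.76 in the survivor infected pool of family 2, -3.62 in the naive infected pool of family 3 and -5.92 in the survivor infected pool of family 4.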

How the results depend on the processing

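Array weights, the family 4 control pools left out, single slides, the covarying set as covariate and 1 value per sequence were chosen after seeing the data. The 5 treatment contrasts called 0 probes under every alternative run, with no replicate block and with each family or array left out too, except that families 1 and 2 alone gave 5 probes for the response of survivors. The 93 probes differing between families became 60 with median centring, 276 with array weights, 38 without both family 4 control pools, 2 in families 1 and 2 alone and 0 in families 3 and 4 alone, and 14 to 80 with a family or array left out. The 37 probes with a differing response became 22 with quantile normalization, 61 with a trended and robust variance, 0 in families 1 and 2 alone and 134 in families 3 and 4 alone, and 0 to 143 with a family or array left out. The 38 probes 2-fold lower in survivor controls became 16 with normexp. They became 128 in families 1 and 2 alone and 101 in families 3 and 4 alone. With a family or array left out they became 39 to 89, where fewer families had to meet the condition. Each of these alternative counts takes in probes higher as well as probes lower in all families. Single slides held fewer pools; the cause of the shifts was not tested. Of 911 values of named probes under alternatives, 893 kept their direction and side of the threshold, 18 were no longer past it and 0 reversed. Most of the 911 belong to probes of the treatment contrasts, which had not passed, so the side they kept was that of no call. These had also been chosen for differing one way in all 4 families, so leaving out a family could not reverse them. All 18 losses were among the probes named for the family tests. Tests per gene, camera and fry on the gene lists were not run because no gene names could be matched. At least 89.2% of probes were well above background on each array.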

Other observations

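The tests on mean effects were planned before they were run, and the test on shared probe IDs was changed after its result was seen. A call in the mean of both histories was expected if a shared change had been missed with 4 pools against 4, and 0 calls were set beforehand to count against one. The mean effect of VHSV over naive fish and survivors called 0 probes in limma, with 273 at an unadjusted p under 0.05, where 204.9 are expected by chance, and a smallest adjusted p of 0.686. R2_1892 was higher after VHSV by 0.58 ± 0.12 (SE) on the log2 scale, in the same direction in 8 of 8 family pairs, and R2_4066 was 1.95-fold higher, in 7 of 8. The mean effect of the first injection over both second injections also called 0 probes, with 266 at an unadjusted p under 0.05 and a smallest adjusted p of 0.726. That bound was too strict. In a simulation added afterwards, with 50 probes changed at each of 4 fold sizes, each mean effect was recovered in 52% of probes at 1.5-fold. At 2-fold, 88% were recovered for VHSV and 74% for the first injection. A shared change of these sizes or smaller thus stays open, and recovery may be lower where fewer probes change.

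Several probe IDs share a stem and differ in a suffix, and such probes may report the same transcript. Over all 229 probes of 47 stems, the median SD of the naive response within a stem was 0.27 of that of random probes. Many of these probes have identical sequences, so that ratio partly compares a probe with itself, and the test was repeated on 94 distinct sequences. The ratio was then 0.47, with an SD of 0.09 within stems against 0.20 for random sequences and a lowest value of 0.10 in 1000 draws. The deposited files do not say what a stem stands for.

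Few probes crossed the background level with treatment. In all 4 pools of survivors given VHSV and in 0 of 4 survivor control pools, 1 of 4305 probes, R2_3065, was well above background, and 0 showed the opposite. For survivor against naive controls these counts were 1, R2_520, and 0, and for the other comparisons 0 and 0. Both probes were named after their values were seen.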
